A study of Arabidopsis thaliana with 6 samples.

How the data were processed

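Poly(A) RNA of Arabidopsis thaliana ovules was sequenced in 6 libraries, 3 labelled wild type and 3 labelled sgd mutant. All came from the qrt1 background, whose pollen stays in tetrads, and were collected at FG1 to FG3, the first stages of embryo sac development. The design text speaks of about 6000 ovules and does not say whether that is per library. RNA was prepared with an RNeasy Plant Mini kit and libraries with the NEBNext Poly(A) and Ultra kits, per the labels' protocols. The labels give each library a genotype and a number from 1 to 3. Nothing in them says that the libraries of a group came from separate plants, so p-values measure only the spread between these samples, which may be technical.

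The values were deposited as FPKM, fragments per kilobase of transcript scaled to mapped fragments, with 2 decimals, per the file headers. Per the submitters' processing notes, the build was TAIR10 and the tools were CASAVA, cutadapt 1.15, TopHat2 2.1.1, RSEM and DESeq2, with no role or order given. Each library lists 30457 features, of which 29889 are nuclear loci, 122 mitochondrial loci, 88 chloroplast loci and 358 features with XLOC numbers. Names came from a RefSeq table of assembly TAIR10.1, which matched 98.1% of the identifiers. Its build name differs from TAIR10, so no coordinates are given. RSEM divides reads between near-identical copies, so single members of such families (the light-harvesting and small Rubisco subunit genes, for example) are uncertain. RAN2, a copy of a widely used Ran GTPase gene, was listed at 0 in 4 libraries and at 52.1 FPKM in another, so a listed 0 need not mean absence. Strand use in counting is not given in the sources used here.

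FPKM are not counts, so depth was estimated from the steps of low values, since 1 fragment in a gene of known length adds a fixed amount. The estimates were 25800000, 33900000 and 39900000 fragments for wild-type libraries 1, 2 and 3, and 23800000, 14100000 and 13200000 for sgd libraries 1, 2 and 3. Between 80.7% and 97.0% of the low values used lay within 0.2 of a whole number of fragments, at the step fitted to these same values. The fragment length was fitted together with the depth, so these are estimates only. On 3 simulated libraries the method erred by at most 1.0%. These were built with the same steps that the method looks for. Their fragments were shorter than the lengths fitted for sgd libraries 2 and 3 (340 and 360 bases), so the error there is not known.

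Genes with a mean of at least 1 FPKM over the 6 libraries (18100 features) were tested with limma 3.58.1 in R 4.3.3, as lmFit and eBayes with a trend on log2(FPKM + 1), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, sgd minus wild type, which understates the change of low genes. The 19 gene lists were tested with camera at an inter-gene correlation of 0.01, adjusted over the 18 lists with at least 2 tested members. Camera compares a list with all other tested features. The lists were also tested with fry, which asks whether the genes of a list move, on balance, one way and makes no comparison with other genes. Of 388 list members, 359 matched the table by symbol and locus, 24 were kept by locus alone and 5 were left out. The test was checked on simulated data for this comparison with 18100 genes: limma recovered 7% of 100 genes changed by 1 on the log2 scale and 61% of 100 changed by 2, with 3 false calls. The simulated noise was independent between genes and between libraries, with no effect shared by libraries of the same number. The false calls therefore do not show how many arise in the real data. The share of summed FPKM from organelle loci was compared with an exact two-sided permutation test.

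The named genes are the 10 largest rises and the 10 largest falls among genes past the threshold with a log2 change of at least 1 and no overlap between groups, and from each list up to 4 tested members with the smallest p, of which some are described and some are not reported here. This rule, the 19 lists, the tests and the alternatives were fixed before the data were examined. Alternatives were pseudocounts of 0.1 and 0.01, no filter, a mean of at least 5 FPKM, rescaling to equal totals, quantile normalization, median-ratio scaling, the replicate number as a block, eBayes without a trend or made robust, array quality weights, camera with an estimated correlation, fry, and leaving out each library in turn. Leaving out both replicate 1 libraries, and median-ratio scaling together with the block, were chosen after seeing the data, as were the gene lists of the closing section. The replicate numbers come from the labels. Deviations from the group means correlated across genes between same-numbered libraries at 0.524, 0.236 and 0.377 for numbers 1, 2 and 3, so the numbers may pair the samples. The labels do not say so and the main fit has no block, so its counts and p-values ignore any pairing. The blocked value is given where it ends a call or moves a count by over 1.5 times. Wild-type library 2 and sgd library 3 also correlated, at 0.354, and wild-type library 3 and sgd library 2 at 0.431, so numbers 2 and 3 are not told apart by this check.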

Results

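RNA of wild-type and sgd mutant ovules was compared at the FG1 to FG3 stages, with 3 libraries per genotype. The comparison asks which transcripts differ between ovules of the mutant and of the wild type early in embryo sac development. The locus mutated in sgd is not given in the sources used here, so its own transcript is not reported. Estimated depth ranged from 13200000 to 39900000 fragments per library and was lower in the sgd libraries than in wild-type libraries of the same number. The files gave 17187 to 18102 features at 1 FPKM or more per library.

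Libraries parted by genotype, and within each genotype library 1 stood apart from the other two. The first principal component held 58.6% of the variance and parted the genotypes, and the second held 30.8% and parted both replicate 1 libraries from the rest. Pearson correlations of log2(FPKM + 1) across genes were 0.946 to 0.991 among wild-type libraries, 0.89 to 0.976 among sgd libraries and 0.747 to 0.875 between genotypes. AT3G06355, a noncoding RNA locus singled out after its values were seen, stood at 44051 FPKM in wild-type library 1 and 33265 FPKM in sgd library 1, against 788 to 2563 FPKM in the other libraries. Chloroplast and mitochondrial loci held 2.18% and 2.08% of the summed FPKM in these libraries and at most 0.0733% in the others. Between genotypes that share was 0.766% ± 1.22 (SD, n = 3) in wild type and 0.740% ± 1.16 (SD, n = 3) in sgd, with p = 0.9 in an exact permutation test whose smallest possible p, with 3 against 3, is 0.1, so that no difference could pass.

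**Figure D1:**
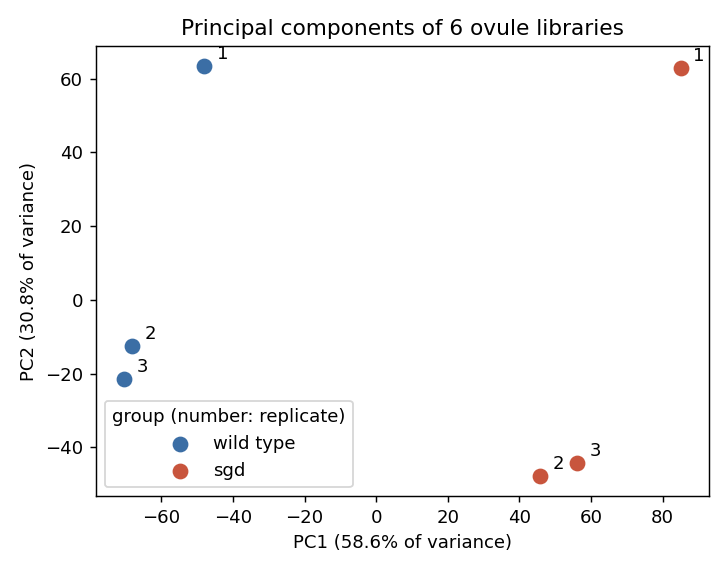
Scores of the 6 libraries on the first and second principal components of log2(FPKM + 1), without units, with colour for genotype and the number for the replicate. The genotypes part along the first axis (58.6% of the variance) and both replicate 1 libraries lie at the top of the second (30.8%).

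Of 18100 features, 3216 changed between genotypes, 2407 higher and 809 lower in sgd ovules (limma, Benjamini-Hochberg adjusted p under 0.05). With a log2 change of at least 1, 2066 were higher and 766 lower. The 3 sgd values lay beyond all 3 wild-type values for 35.6% of tested features, where chance gives 10%. With the replicate block 7376 changed, 4793 up and 2583 down, and 2353 of the 2407 risen and 796 of the 809 fallen features were called again in the same direction. The share of calls that were higher in sgd depended on scaling: 74.8% as deposited, 61.2% after rescaling to equal totals, 52.1% after median-ratio scaling and 45.8% after quantile normalization. The median change of all tested features was 0.13 as deposited and 0.00065 after median-ratio scaling, so list medians below are given relative to the median of all features. Without both replicate 1 libraries, chosen after seeing the data, 8787 changed. Leaving out wild-type library 2, wild-type library 3 or sgd library 3 gave 1961, 2044 and 2113. Fallen features numbered 2640 after rescaling to equal totals, 3286 after median-ratio scaling, 3726 after quantile normalization, 407 without wild-type library 2 and 420 without wild-type library 3, and risen features 1554 without wild-type library 2 and 1535 without sgd library 3.

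The largest rises included genes listed at 0 in all wild-type libraries, which need not mean absence. AT1G62333 was listed at 0 in all wild-type libraries and at 348, 447 and 452 FPKM in sgd libraries 1, 2 and 3. AT2G44130, of an F-box family, was listed at 0 in wild type and at 168, 76.0 and 124 FPKM in sgd, and AT2G38900, of a proteinase inhibitor family, at 0 and at 63.9, 92.2 and 68.3 FPKM. AT1G56100 rose from 1.39 ± 0.971 to 694 ± 147 FPKM (SD, n = 3), a log2 change of 8.23 (SE 0.33, limma adjusted p = 1.05e-06). HIS1-3 (AT2G18050), a linker histone gene induced by drought, rose from 3.92 ± 1.29 to 415 ± 210 FPKM (SD, n = 3). AT3G19030, AT2G33830 and DIP2 (AT5G03210) rose by 6.24, 5.91 and 5.76 on the log2 scale, and BAN and DFR complete this group. All 20 genes of the largest rises and falls passed under every alternative run in which they were tested. They were chosen from these same data for size and lack of overlap, which favours such an outcome.

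The largest falls included a MYB-related gene, a cyclin gene and genes of enzymes. MEE3 (AT2G21650), a small MYB-related gene, fell from 253 ± 133 to 3.36 ± 2.60 FPKM (SD, n = 3), by 5.93 on the log2 scale (SE 0.55, limma adjusted p = 0.000124). CYCD3;1 (AT4G34160), a D-type cyclin that promotes entry into the cell cycle, stood at 13.2, 24.0 and 17.7 FPKM in wild-type libraries 1, 2 and 3 and was listed at 0 in all sgd libraries. BRS1 (AT4G30610), a serine carboxypeptidase gene, fell from 111 ± 23.3 to 4.19 ± 2.37 FPKM, and MSRB9 (AT4G21850), a methionine sulfoxide reductase gene, from 37.6 ± 15.4 to 0.387 ± 0.293 FPKM (SD, n = 3). AT2G34700, AT5G26220, AT5G47600, the adenylyl-sulfate kinase gene AKN2 (AT4G39940), the fatty acid desaturase gene ADS1 (AT1G06080) and the beta-amylase gene BAM5 (AT4G15210) fell by between 4.68 and 3.77 on the log2 scale.

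Of 15 tested genes of flavonoid and proanthocyanidin synthesis, the pathway of seed coat pigment, 12 rose, none fell and 3 did not pass, and adjusted over the list alone 13 rose. BAN (AT1G61720), anthocyanidin reductase, rose from 0.780 ± 0.0889 to 141 ± 60.8 FPKM, and DFR (AT5G42800), dihydroflavonol reductase, from 0.107 ± 0.0924 to 63.0 ± 22.4 FPKM (SD, n = 3). GSTF12 (AT5G17220), which carries flavonoids to the vacuole, and the proton pump gene AHA10 (AT1G17260) rose by 5.14 (SE 0.29) and 4.73 (SE 0.28) on the log2 scale. The list median lay 2.32 above that of all features (camera adjusted p = 6.47e-10). The list call was lost with an estimated correlation (adjusted p = 0.511).

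Of 27 tested mitosis and cytokinesis genes 13 fell, none rose and 14 did not pass, 20 fell adjusted over the list alone, and with the replicate block 23 fell. The kinesin gene HIK (AT1G18370) went from 43.6 ± 9.13 to 11.5 ± 6.16 FPKM, the aurora kinase gene AUR1 (AT4G32830) from 36.1 ± 9.16 to 11.2 ± 4.32 FPKM, and the spindle gene TPX2 (AT1G03780) from 42.3 ± 2.52 to 14.7 ± 5.91 FPKM (SD, n = 3). CYCB1;4 (AT2G26760), a B-type cyclin, fell by 1.57 on the log2 scale (SE 0.35). Of 18 DNA replication genes 8 fell, none rose and 10 did not pass, 16 fell adjusted over the list alone, and 16 fell with the block. TSO2 (AT3G27060), a ribonucleotide reductase subunit, went from 59.8 ± 10.5 to 23.3 ± 11.3 FPKM (SD, n = 3, limma adjusted p = 0.0214), and the licensing genes CDC6 (AT2G29680) and CDT1A (AT2G31270) fell by 1.14 and 1.24 on the log2 scale. These 3 calls were lost when single libraries were left out, with limma adjusted p up to 0.0667, 0.143 and 0.116, and with no filter (adjusted p = 0.0503, 0.0823 and 0.0833). The counts moved both ways: with median-ratio scaling 24 mitosis and all 18 replication genes fell, and with no filter 6 and 1. Without wild-type library 2 or 3, 7 and 6 mitosis genes fell and no replication gene passed limma (13 at an unadjusted p under 0.05 in each), and fallen replication genes numbered 1 without wild-type library 1, 4 without sgd library 1, 14 without sgd library 2 and 1 without sgd library 3. The list medians lay at -1.39 and -1.25 relative to all features (camera adjusted p = 9.76e-12 and 1.78e-09), and both list calls were lost with an estimated correlation (adjusted p = 0.511 for each). With fry neither list passed (adjusted p = 0.118 for each).

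**Figure D2:**
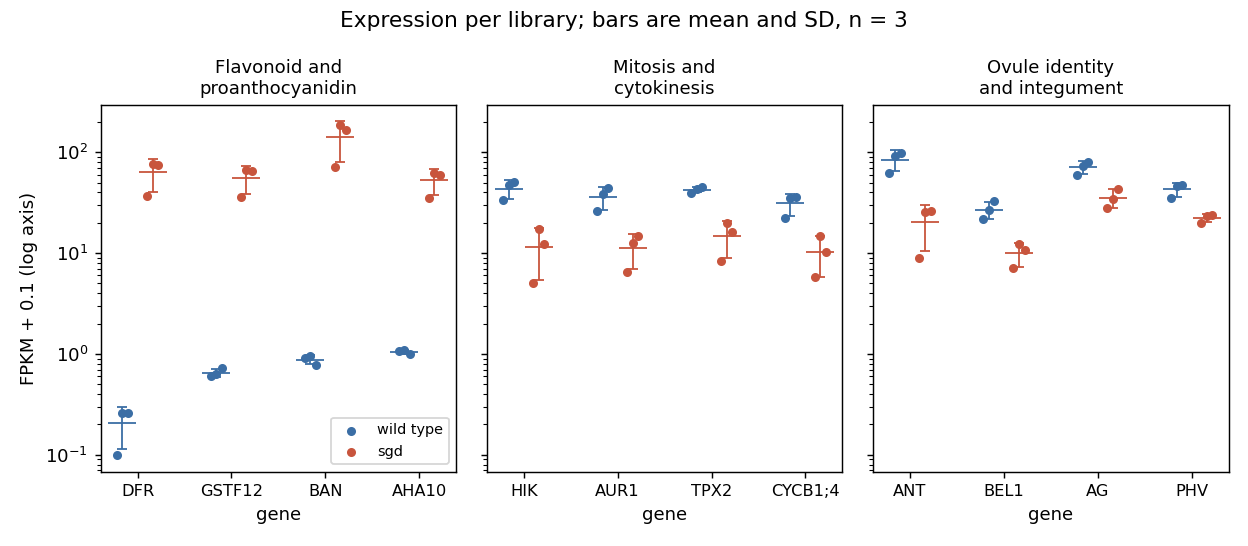
FPKM plus 0.1 on a log axis per library for the 4 named genes of the flavonoid and proanthocyanidin, mitosis and ovule identity lists, with mean and SD over 3 libraries per genotype. BAN stands at 0.780 FPKM in wild type and 141 FPKM in sgd, while HIK goes from 43.6 to 11.5 FPKM and ANT from 84.4 to 20.3 FPKM.

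Ovule identity and integument genes fell in 5 of 26 tested members and none rose, with 5 fallen adjusted over the list alone, 15 fallen and 1 risen with the replicate block and 17 fallen and 1 risen with median-ratio scaling. Fallen members numbered 2 without wild-type library 2, wild-type library 3 or sgd library 3 and 3 without sgd library 2. ANT (AT4G37750), a regulator of ovule primordium and integument growth, went from 84.4 ± 19.6 to 20.3 ± 9.90 FPKM, and the homeobox gene BEL1 (AT5G41410) from 26.9 ± 5.30 to 9.86 ± 2.64 FPKM (SD, n = 3). The list median lay at -0.70 relative to all features (camera adjusted p = 2.36e-05, and adjusted p = 0.572 with an estimated correlation). With fry the ovule list did not pass (adjusted p = 0.231). Of 25 meiosis genes 4 fell and none rose, 2 fell adjusted over the list alone, and 7 fell and 1 rose with the block. With median-ratio scaling 11 meiosis genes fell, with quantile normalization 14 and without both replicate 1 libraries 9. Only 2 fell with no filter or without wild-type library 1, and 1 without wild-type library 2, wild-type library 3 or sgd library 3. DMC1 (AT3G22880), the meiotic recombinase, fell from 26.3 ± 6.42 to 7.86 ± 4.16 FPKM (SD, n = 3, limma adjusted p = 0.0137). The meiosis median lay at -0.61 (camera adjusted p = 0.000339, and adjusted p = 0.572 with an estimated correlation), and the fry adjusted p was 0.268.

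Of 10 tested embryo sac genes, from a list of 25, 3 fell and none rose, and 3 fell adjusted over the list alone. The counts were 2 risen and 2 fallen without both replicate 1 libraries, and 1 risen and 3 fallen without sgd library 1 or with no filter. AT1G26795 went from 21.2 ± 5.61 to 0.840 ± 1.104 FPKM, and the egg cell genes EC1.2 (AT2G21740) and EC1.1 (AT1G76750) from 2.41 ± 1.25 to 0.0633 ± 0.110 and from 4.70 ± 2.48 to 0.913 ± 0.152 FPKM (SD, n = 3). EC1.3 (AT2G21750), also an egg cell gene, stood at 4.42 ± 2.72 and 1.95 ± 1.81 FPKM (SD, n = 3). Its groups overlapped and it did not pass (limma adjusted p = 0.281). EC1.1 lost its call without wild-type library 1 or 2 (limma adjusted p = 0.0846 and 0.0811), with no filter (adjusted p = 0.0506) and without both replicate 1 libraries (adjusted p = 0.0556). The list median lay at -0.79 (camera adjusted p = 0.00296, and adjusted p = 0.511 with an estimated correlation). The list call was also lost with no filter (adjusted p = 0.0903), with median-ratio scaling (adjusted p = 0.0619, and 0.0901 together with the block), without wild-type library 1 (adjusted p = 0.0731) and without both replicate 1 libraries (adjusted p = 0.336). With fry the list did not pass (adjusted p = 0.118). Not relative to all features, the median change was -0.66. Over the 4 members with a mean of at least 5 FPKM, of which 1 fell and 0 rose, it was 0.11, and there the list did not pass (camera adjusted p = 0.296).

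Genes of heat shock rose in 12 of 13 tested members, and in 13 adjusted over the list alone. DREB2A (AT5G05410), a regulator of drought and heat responses, rose from 8.64 ± 8.46 to 268 ± 48.4 FPKM, and the chaperone gene HSP101 (AT1G74310) from 9.42 ± 2.63 to 56.1 ± 17.8 FPKM (SD, n = 3). The list median lay 2.45 above that of all features (camera adjusted p = 1.75e-08, and adjusted p = 0.511 with an estimated correlation). Of 21 wounding, touch and jasmonate genes, a list chosen to show handling, 10 rose and 2 fell, and 10 and 3 did so adjusted over the list alone. ERF104 (AT5G61600) and WRKY33 (AT2G38470) rose by 4.68 and 3.11 on the log2 scale, and CBF1 (AT4G25490), known from cold responses, by 4.42. The median of the wounding list lay 0.88 above that of all features (camera adjusted p = 0.00557). The list call was lost with the replicate block (adjusted p = 0.157), with rescaling to equal totals (adjusted p = 0.0522) and with median-ratio scaling and the block together (adjusted p = 0.0516). It was also lost without both replicate 1 libraries (adjusted p = 0.0657) and with an estimated correlation (adjusted p = 0.572). With fry the wounding list did not pass (adjusted p = 0.0811).

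Auxin genes went both ways, with 5 of 13 fallen and 3 risen, and 5 and 4 adjusted over the list alone. YUC1 (AT4G32540), an auxin synthesis gene, stood at 4.55, 6.11 and 5.18 FPKM in wild-type libraries 1, 2 and 3 and was listed at 0 in all sgd libraries. WES1 (AT4G27260), whose product conjugates auxin, stood at 156, 19.3 and 33.7 FPKM in sgd libraries 1, 2 and 3 against 1.42 ± 0.180 FPKM in wild type (SD, n = 3, limma adjusted p = 0.000977). Of 11 cytokinin genes 3 fell and 1 rose, also adjusted over the list alone, with the response regulator gene ARR4 (AT1G10470) at 23.8 ± 13.6 and 5.37 ± 0.868 FPKM (SD, n = 3), a call lost with no filter (limma adjusted p = 0.0561). No cytokinin gene was called risen without wild-type library 2, wild-type library 3 or sgd library 3. Neither list passed (camera adjusted p = 0.0823 and 0.0896). The auxin list passed with no filter (adjusted p = 0.0337) and without wild-type library 2 (adjusted p = 0.0446), and the cytokinin list, with 1 fallen member without wild-type library 2 or 3, passed without wild-type library 1 (adjusted p = 0.0456), sgd library 1 (adjusted p = 0.0225) or both (adjusted p = 0.0398).

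Genes of mRNA decay and the RNA exosome showed 2 rises and no fall among 38 tested, also adjusted over the list alone, 8 rises and 2 falls with the replicate block and 5 rises and 2 falls with median-ratio scaling. Both rises were deadenylase genes. CAF1a (AT3G44260) rose from 21.04 ± 12.59 to 224 ± 76.5 FPKM and CAF1b (AT5G22250) from 7.73 ± 1.52 to 71.0 ± 40.7 FPKM (SD, n = 3). The list did not pass (camera adjusted p = 0.987), and its median, -0.04 relative to all features, was 0.09 before that. Of 17 genes of sporocyte fate and small RNAs 2 rose and 1 fell, and of 16 genes of DNA methylation and silencing 3 rose and 1 fell, with the same counts adjusted over the list alone. With the replicate block 2 rose and 3 fell in the first and 3 rose and 3 fell in the second, and with median-ratio scaling falls outnumbered rises, at 4 against 2 and 5 against 3. With 1 library left out, at most 1 fell in each. Only 1 rose in each without wild-type library 2, wild-type library 3, sgd library 2 or sgd library 3. DRM2 (AT5G14620), a de novo DNA methyltransferase gene in both lists, rose from 12.8 ± 1.87 to 31.4 ± 1.80 FPKM (SD, n = 3, limma adjusted p = 0.00609). MET1 (AT5G49160), the maintenance enzyme, stood at 45.7 ± 7.36 and 21.6 ± 9.08 FPKM (SD, n = 3, limma adjusted p = 0.0468), a call lost without single libraries (adjusted p up to 0.134), with no filter (adjusted p = 0.0833) and with eBayes without a trend (adjusted p = 0.0514). Neither list passed (camera adjusted p = 0.416 and 0.372). For the first, the median change was 0.03 (-0.09 relative to all features) and the mean change -0.02. Of 4 tested salicylate genes, from a list of 10, WRKY70 (AT3G56400) rose and PR1 (AT2G14610) fell, with the same counts adjusted over the list alone. The salicylate list did not pass (camera adjusted p = 0.987), with a median change of 0.19 (0.07 relative to all features) and a mean change of -0.03.

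Markers of other cell types moved with the genotype, beside each of the groups above. Of 9 tested pollen and sperm genes, from a list of 16, 6 rose and none fell, also adjusted over the list alone. VGD1 (AT2G47040), a pectin methylesterase gene of pollen tubes, stood at 6.4, 2.09 and 2.81 FPKM in wild-type libraries 1, 2 and 3 and at 58.8, 54.8 and 27.6 FPKM in sgd libraries 1, 2 and 3, and AGP6 (AT5G14380) rose from 2.46 ± 1.62 to 24.1 ± 9.88 FPKM (SD, n = 3). The median lay 1.41 above that of all features (camera adjusted p = 0.000339, and adjusted p = 0.511 with an estimated correlation). Of 4 tested anther and tapetum genes, from a list of 15, 3 rose, also adjusted over the list alone (1 without wild-type library 3). With no filter 3 of 9 rose, and the median change was 0.04. SPL8 (AT1G02065) went from 1.85 ± 0.539 to 24.2 ± 9.84 FPKM (SD, n = 3). That list call (camera adjusted p = 0.0220) was lost with the replicate block (adjusted p = 0.134), with median-ratio scaling (adjusted p = 0.0583), with rescaling to equal totals (adjusted p = 0.0659), with no filter (adjusted p = 0.529) and with an estimated correlation (adjusted p = 0.527). Of 22 photosynthesis genes 7 rose, 9 adjusted over the list alone, 12 with the block and 11 with median-ratio scaling. Risen members numbered 4 without wild-type library 3 or sgd library 2 and 3 without sgd library 3. GAPA (AT3G26650) stood at 40.9 ± 10.9 and 112 ± 8.55 FPKM (SD, n = 3, camera adjusted p for the list = 0.00150, and adjusted p = 0.572 with an estimated correlation). With fry the photosynthesis list did not pass (adjusted p = 0.118). Of 8 tested carpel wall and style genes, from a list of 13, 4 fell, and 5 adjusted over the list alone. With the block 5 fell and 1 rose, and 2 fell without wild-type library 2 or 3. STY1 (AT3G51060) went from 70.3 ± 33.2 to 5.24 ± 3.61 FPKM (SD, n = 3). The list median lay at -1.05 (camera adjusted p = 0.00182, and adjusted p = 0.511 with an estimated correlation), a call also lost with median-ratio scaling and the block together (adjusted p = 0.0561). With fry the carpel list did not pass (adjusted p = 0.0574). The 16 seed maturation, endosperm and embryo genes reached at most 0.42 FPKM in any library and could not be tested.

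**Figure D3:**
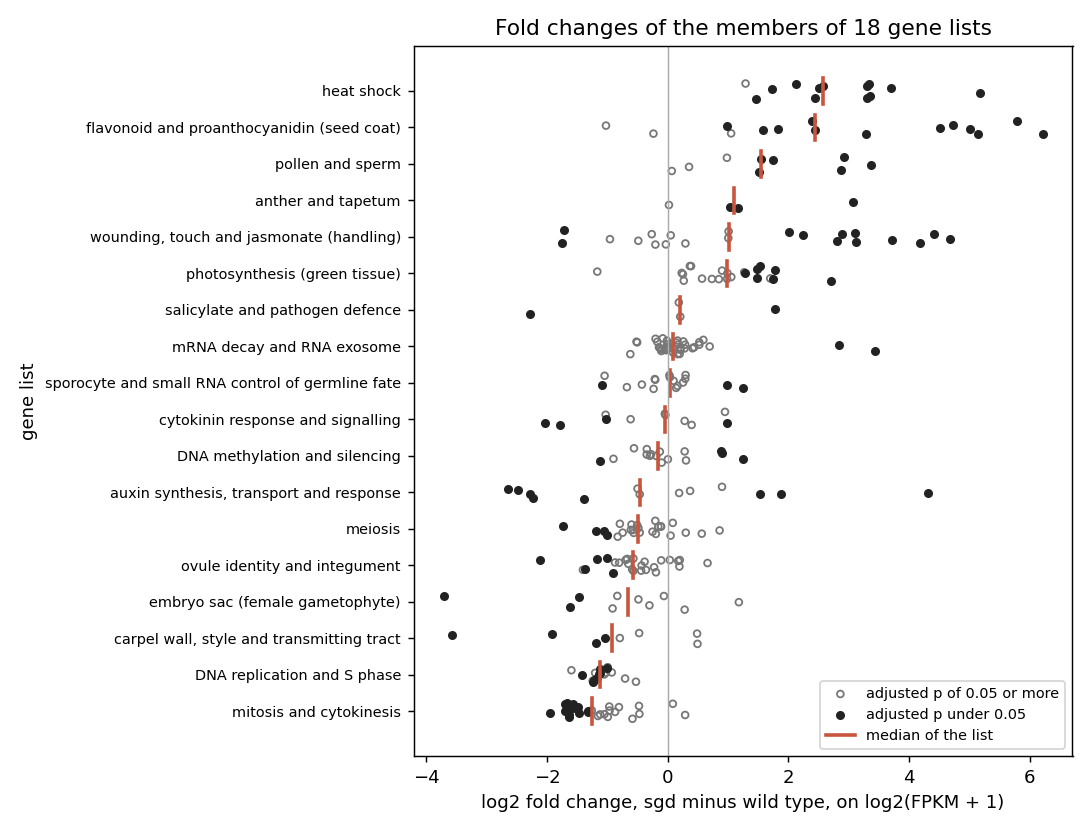
Log2 fold changes, sgd minus wild type on log2(FPKM + 1), of each tested member of 18 gene lists, with filled points for an adjusted p under 0.05 and a bar at each list's median. Heat shock and flavonoid genes lie furthest to the right, and DNA replication and mitosis genes have the lowest medians.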

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

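Leaving out both replicate 1 libraries, and median-ratio scaling with the replicate block, were chosen after the results were seen. The count of 3216 changed features stayed within 1.5 times under other pseudocounts, filters and eBayes settings (2242 to 3418). It rose to 6798 with rescaling to equal totals, 6872 with quantile normalization, 6861 with median-ratio scaling, 7376 with the replicate block, 7159 with median-ratio scaling and the block, 8787 without both replicate 1 libraries and 12611 with array quality weights, whose estimation stopped before it converged. Leaving out 1 library gave 1961 (without wild-type library 2) to 4302 (without sgd library 1), with 2044 without wild-type library 3 and 2113 without sgd library 3. There fallen features ranged from 407 to 968 and risen from 1535 to 3496, while fallen features numbered 2640 with equal totals, 3286 with median-ratio scaling and 3726 with quantile normalization. Of 12 lists past the threshold, none passed with camera and an estimated correlation (0 also at an unadjusted p under 0.05; median estimated correlation 0.689). With fry, which tests a list against no change and not against other genes, 4 passed (heat shock, flavonoid, anther and pollen). All 4 rose, and no fallen list passed fry. Leaving out 1 library gave 12 or 13 lists, and the other alternatives 8 to 12. The replicate block ended the calls of the wounding and the anther lists and no other list call. No named gene with a call changed sign and no called list's test changed direction. The groups of each named gene with a call did not overlap, so leaving out a library could not turn its sign. The median of the embryo sac list was -0.66 over 10 members and 0.11 over the 4 with a mean of at least 5 FPKM, where its call was lost. Of 82 named genes past the threshold, 59 passed without each library in turn and 23 (16 of them fallen) were lost without some library. The organelle share difference, -0.0259 percentage points, ranged from -0.698 to 0.681 when 1 library was left out, turning positive without wild-type library 1 (0.681), sgd library 2 (0.313) or sgd library 3 (0.307), and no setting had enough libraries for a call. Why the results differ between settings was not tested. Fits that leave libraries out have fewer samples, yet the count of changed features rose without sgd library 1 (4302) and without both replicate 1 libraries (8787). Depth was lower in sgd libraries 2 and 3 (14100000 and 13200000 fragments, estimated). There 1 fragment per kilobase was worth an estimated 0.0711 and 0.0756 FPKM, which limits what can be said of genes near that level. CYCD3;1 (13.2 to 24.0 FPKM in wild type) and YUC1 (4.55 to 6.11 FPKM in wild type) lay far above it and were listed at 0 in all sgd libraries.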

Other observations

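The test for a later stage was written after part of the embryo sac result was seen, the lists of clock, early endosperm, abscisic acid response, starvation and abundant pollen genes were chosen after the changed genes were seen, and weighing the quartiles of the endosperm genes and leaving LHY out of the clock test were added after their results were seen. Genes of the abscisic acid response, the hormone of drought and seed dormancy, rose in sgd ovules in 9 of 14 tested members, and none fell. The protein phosphatase genes HAI1 and ABI1 rose from 4.97 ± 0.936 to 71.9 ± 21.2 FPKM and from 11.55 ± 1.296 to 57.9 ± 4.97 FPKM (SD, n = 3), and the transcription factor gene RD26 from 2.1 ± 0.975 to 26.7 ± 6.98 FPKM. KIN2 stood at 330, 79.9 and 122 FPKM in sgd libraries 1, 2 and 3. The list passed camera (adjusted p = 2.06e-08) and not with an estimated correlation (adjusted p = 0.182). Of 11 genes induced by darkness or sugar starvation 6 rose and none fell, with the asparagine synthetase gene ASN1 at 36.5 ± 18.5 and 195 ± 52.3 FPKM (SD, n = 3, camera adjusted p for the list = 0.000631, and adjusted p = 0.280 with an estimated correlation).

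Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many changed genes as the genotypes did (the genotype split itself, with 3216), and the highest other split gave 1. With 10 splits no share under 0.05 can be reached. Every other split mixes the genotypes within a side, which puts the genotype difference into the spread. The counts of those splits therefore do not show how many calls chance gives.

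Of 15 genes of flavonoid and seed coat pigment synthesis 12 rose in sgd ovules. Fertilized seeds among the sgd ovules would bring endosperm transcripts: over 12 early endosperm genes the median difference was 0.0746 on log2(FPKM + 0.1), under the bound of 0.5 set against seeds beforehand but with quartiles of 0 and 1.32, and none had an sgd mean of 1 FPKM or more. However, 8 of the 12 had a higher mean in sgd and 2 were at 0 in all libraries, AGL62 going from 0.0433 ± 0.0379 to 0.733 ± 0.424 FPKM (SD, n = 3), so values this near the floor leave a small share of seeds open. The median of the embryo sac genes, -0.66, decides nothing about collection at a later stage: it meets the bound set against one, but that bound was written after part of the fall was seen. The median was also only -0.06 without both replicate 1 libraries. The list call was lost in camera with an estimated correlation (adjusted p = 0.511), but no list passed that test, so it cannot judge this fall. A difference in stage, seeds among the ovules and an effect of the genotype on the ovule coat, itself untested, cannot be told apart here.

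Of 9 tested pollen and sperm genes 6 rose in sgd ovules. Pollen carried over with the ovules is a candidate source: of 25 detectable genes abundant in pollen, 100% had a higher mean in sgd (median FPKM 1.82, 0.890 and 1.04 in wild-type libraries and 16.2, 15.2 and 7.88 in sgd libraries 1, 2 and 3), and AGP23, among the highest, reached 59.3 ± 16.7 FPKM in sgd (SD, n = 3). Their median log2 ratio of sgd library 3 to library 2 was -1.06, against 0.14 for other risen genes, below all of 10000 random lists of risen genes. VGD1 of the first list already differed this way, at 54.8 FPKM in sgd library 2 and 27.6 FPKM in sgd library 3. Genes that vary together for any reason would also lie apart from such random lists, so this ratio does not favour carry-over above other causes. Pollen genes switched on in ovule cells gene by gene would scatter more, and the SD of that ratio, 0.375, lay at the 12.7th percentile of random lists, too high to exclude it. An effect of the genotype that turns these genes on together was not tested.

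LHY, a clock gene expressed around dawn, fell in sgd ovules, from 12.6, 49.7 and 44.9 FPKM in wild-type libraries 1, 2 and 3 to 2.42, 1.47 and 0.47 FPKM in sgd (limma adjusted p = 0.000737). Evening-phased clock genes had a median log2 change of 1.16 (7 of 9 rose, TOC1 among them) and morning-phased genes one of -0.16 (2 of 11 rose, 3 fell), a difference of 1.32. The evening list passed camera (adjusted p = 2.60e-05) and not with an estimated correlation (adjusted p = 0.182). Without LHY, whose fall prompted the test and which is in the morning list, the morning median was -0.14. This is consistent with collection at different times of day, although the morning list went both ways and did not pass (camera adjusted p = 0.105). The collection times are not given in the sources used here, so a changed clock in the sgd genotype, with the same difference of 1.32, cannot be told apart from it.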
